A study of Mus musculus with 16 samples.

How the data were processed

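RNA was profiled in liver cells of c129/S3 mice that had been sorted by the surface antigen MIC1-1C3 (M) and by CD133, the product of Prom1. Cells positive for both (M+133+) or negative for both (M-133-) came from untreated livers or from livers of mice fed 0.1% DDC for 2 weeks. DDC (3,5-diethoxycarbonyl-1,4-dihydrocollidine) blocks ferrochelatase, the last enzyme of heme synthesis, and is used to induce a ductular reaction in mice. Per the labels, RNA was amplified as cDNA, labelled with Cy3 and hybridized to Agilent mouse arrays in 1 colour. The 16 arrays held 14 biological samples, since M+133+ untreated sample 1 and M-133- untreated sample 2 had 2 repeat arrays each. The groups were M+133+ untreated (n = 4), M-133- untreated (n = 2), M+133+ DDC (n = 4) and M-133- DDC (n = 4).

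The deposited array files give each spot's processed signal as an intensity, background-subtracted and detrended within the array by Agilent Feature Extraction 10.5.1.1, and not normalized between arrays. Per the file headers they also hold the raw spot mean and the local background median, again as intensity. A deposited table from the authors gives signed linear fold changes of group means for 4 comparisons, and false discovery rates in percent. Limma is named in the submitters' processing notes, but how the authors normalized or tested those values is not stated. This table was used for comparison only, and its columns of calls were left out. The array annotation is on mouse build mm9. Of 41174 probes other than controls, 32844 were matched to a current gene name in a RefSeq table of assembly GRCm38.p6, which was used for names only. They were matched by accession (26726), symbol (5189) or synonym (929). The other 8330 kept the name in the file.

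The log2 processed signal had the 75th percentile of its array subtracted, and every level given is on this scale. Repeat spots of a probe were averaged, then repeat arrays of a sample. A probe was kept if the scanner software called it well above background in a share of at least 0.5 of the samples of at least 1 group. Of several kept probes of a gene, the brightest over all samples was used, which left 23281 genes of 28029 names. Groups were compared with limma 3.58.1 in R 4.3.3, by linear models on all 14 samples with moderated variances and an intensity trend, two-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and SE is the moderated standard error of a log2 difference. The comparisons were M+133+ against M-133- cells in each treatment, DDC against untreated in each sort, and the interaction of both. Where no array of a group had a gene well above background, the fold was computed against the dimmest value called well above background on each array and is given as "at least". Probes of near-identical paralogs (Chil3 and Chil4, and the Cyp2c, Ugt1a, Serpina3, Saa, Sult3a and hemoglobin families) can read each other's transcripts. Which member was measured is therefore uncertain.

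A total of 21 gene lists were tested with limma's camera, with a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the 21 lists of a comparison. They covered bile duct epithelium, liver progenitor markers of the literature, hepatocyte, Kupffer cell and macrophage, sinusoidal and vascular endothelium, stellate cell and fibroblast, B cell, T and NK cell, neutrophil, erythroid and platelet, proliferation, heme and porphyrin metabolism, Nrf2 antioxidant response, interferon response, chemokines with cytokines and acute phase, extracellular matrix with proteases and integrins, Notch, Wnt, Hedgehog and primary cilium, epithelial junctions and keratins, and immediate early and heat shock genes. Where both groups had n = 4, list means per sample were also compared by an exact permutation test, two-sided, whose smallest possible p was 0.0286. Lists, comparisons, tests, filters, the alternatives other than those described as chosen after seeing the data, and the rule for named genes were fixed before the data were examined.

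The rule named Prom1 first. It then named the 6 largest increases and the 6 largest decreases per comparison among called genes whose values did not overlap between groups, leaving out clone-like identifiers. It added up to 4 called members per list and comparison, and the 3 largest interactions per direction. The other named genes are members of a fixed list given with their values, or genes of a small count or of a pattern, which were chosen after their values were seen.

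The 75th percentile signal ran from 602.8 to 2732.2 intensity units, and 59.8% to 77.1% of probes were well above background. The calls were tested on simulated data, with 100 changed genes per fold size among 23281 genes. At 4-fold, 2% of changed genes were recovered for the untreated sort comparison, 6% for the DDC sort comparison, 5% for DDC in M+133+ cells, 5% for DDC in M-133- cells and 0% for the interaction. At 16-fold the shares were 37%, 47%, 52%, 33% and 10%, in the same order, with 4, 7, 2, 0 and 2 false calls per comparison. In the data the sort comparisons called 2072 and 3015 genes, far more than were changed here. The adjustment is milder where more genes change, so the simulated shares may be too low for those comparisons. A 30-gene list shifted 2-fold was called in all 5 comparisons, and 0 of the 20 other lists were. The simulated genes varied independently of each other. The 0 therefore does not show how often lists are called falsely where genes vary together. The alternatives were quantile normalization, normexp background correction with an offset of 50, other probe filters, the mean of a gene's probes, other limma settings, slide or replicate number as a block, repeat arrays entered singly, and each sample left out in turn. Figures were drawn with matplotlib 3.10.9 from the computed values.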

Results

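Expression was measured on 16 arrays from 14 samples of sorted mouse liver cells, asking how M+133+ cells, sorted as candidate progenitors of the adult liver, differ from M-133- cells and how each population differs after DDC feeding. There were 4 M+133+ and 2 M-133- samples from untreated livers, and 4 of each from livers of DDC-fed mice. The 75th percentile signal was lowest for M-133- untreated sample 1 (602.8 intensity units). Next lowest was 1 array of M-133- untreated sample 2 (705.9), whose repeat array reached 2080.8. Between 59.8% and 77.1% of probes per array were well above background. Correlations across genes between different samples of a group ran from 0.813 to 0.902, and those between arrays of different sorts from 0.669 to 0.786. Those between repeat arrays were 0.833 for M-133- untreated sample 2 and 0.907 for M+133+ untreated sample 1. Genes are not independent replicates. The number of arrays, above all the 2 M-133- untreated samples, limits the precision. The median log2 difference over all genes was -0.10 and 0.27 for the sort comparisons in untreated and DDC livers, 0.08 and -0.33 for DDC in M+133+ and M-133- cells, and 0.37 for the interaction. Differences near these shifts carry no direction of their own.

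Prom1, the gene of the CD133 antigen used for sorting (probe on chromosome 5, mm9, 44385331 to 44385390), served as a check of the labels. Its log2 level was 1.61 ± 0.31 (SD, n = 4) in M+133+ and -7.99 ± 0.42 (SD, n = 2) in M-133- cells of untreated livers, and 1.55 ± 0.66 (SD, n = 4) and -6.39 ± 2.16 (SD, n = 4) after DDC. Every M+133+ sample lay above every M-133- sample, although M-133- DDC sample 2, at -3.44, was well above background. A dimmer probe of Prom1 gave the same order, and was well above background in M-133- untreated sample 1 (-4.83), in 1 of the 2 arrays of untreated sample 2, and in M-133- DDC samples 2 and 4 (-6.65 and -5.95).

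**Figure D1:**
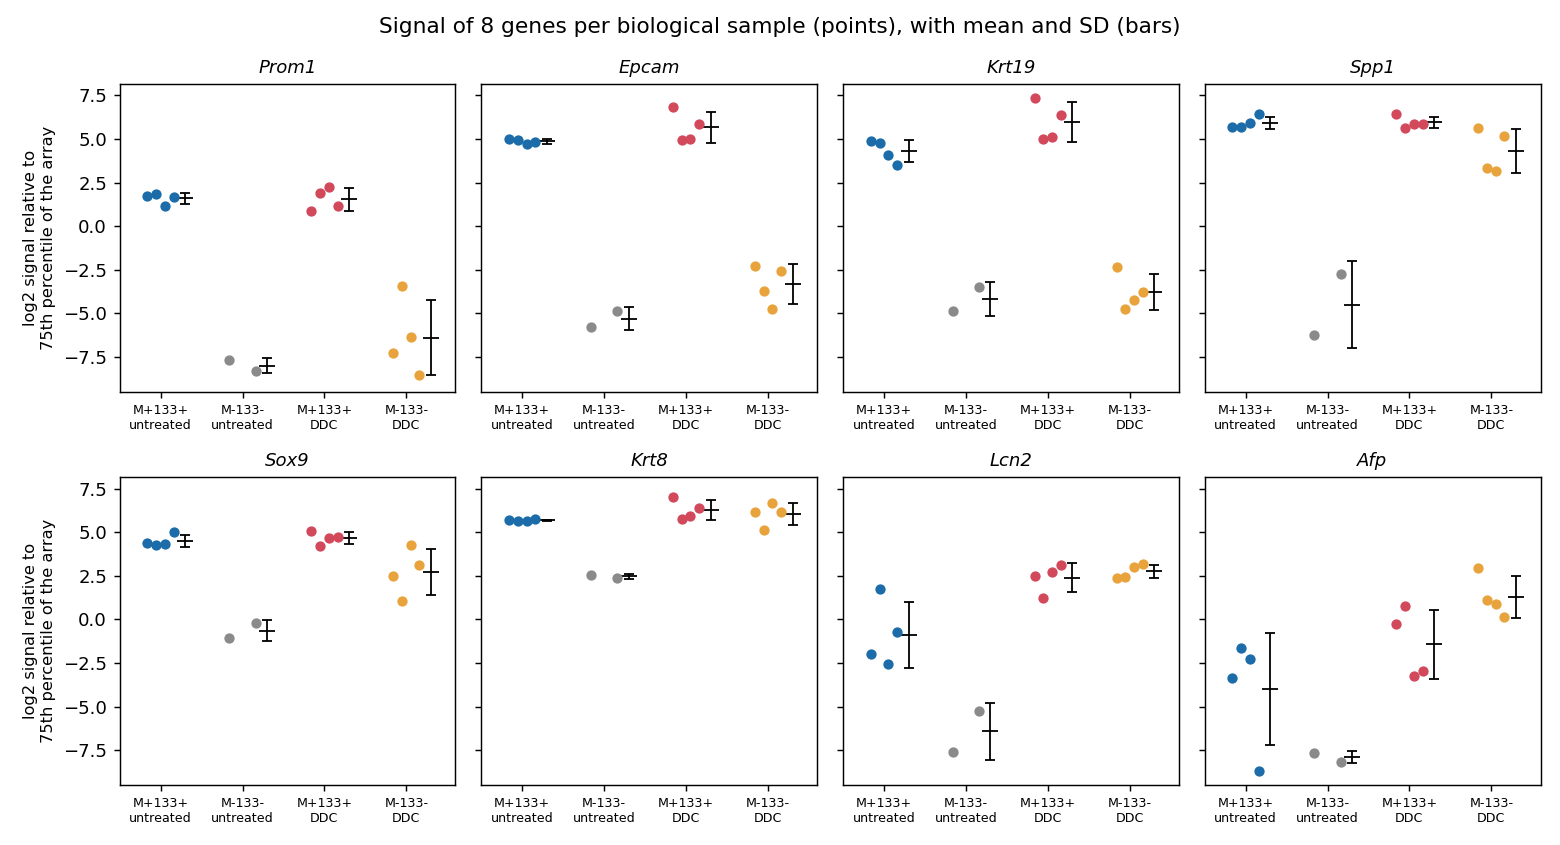
Log2 signal relative to the 75th percentile of the array for 8 genes, in the 4 groups on the horizontal axis; points are biological samples and bars are the group mean and SD. Epcam and Krt19 stayed low in M-133- cells after DDC (means -3.31 and -3.77), whereas Spp1, Krt8 and Lcn2 reached 4.32, 6.05 and 2.76 there.

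The sort comparison in untreated livers asked what distinguishes M+133+ from M-133- cells before injury. M+133+ cells had high levels of genes of the bile duct epithelium. Epcam, an epithelial adhesion molecule, was 1146-fold higher (log2 difference 10.16, SE 0.72, adjusted p = 2.13e-06; 4.87 ± 0.13, n = 4, against -5.29 ± 0.64, n = 2). Spp1, which encodes osteopontin, was higher by 10.43 on the log2 scale (SE 0.81, adjusted p = 5.01e-06) and Krt19, a keratin of bile ducts, by 8.51 (SE 0.81, adjusted p = 1.85e-05). Of the 28 bile duct genes tested, 22 were higher and 0 lower. Adjusted over the list alone, 23 were higher and 1 lower, with a list median of 5.07 (adjusted p = 1.85e-29). The list of epithelial junctions and keratins shared this direction. Of its 30 members 23 were higher and 1 lower (25 and 1 adjusted over the list alone), with a median of 4.74 (adjusted p = 5.1e-26). Among them were the claudins Cldn7 (log2 difference 8.47) and Cldn8 (at least 177-fold, adjusted p = 2.13e-06). Both calls held with an estimated correlation, at adjusted p = 0.000324 and 6.41e-05.

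Other genes with the largest increases in M+133+ cells were F2rl1, a protease-activated receptor (at least 951-fold, adjusted p = 0.0026), Adgrg7, an adhesion receptor (at least 934-fold, adjusted p = 1.69e-05), and Rassf9 (at least 563-fold, adjusted p = 6.16e-06). They also included Kcnk1, a potassium channel (at least 367-fold, adjusted p = 2.13e-06), Elf3, an epithelial transcription factor (at least 347-fold, adjusted p = 0.000482), and Ddit4l (log2 difference 11.17, adjusted p = 0.00182). Progenitor markers of the literature went both ways. Of 19 tested, 8 were higher and 3 lower (10 and 3 adjusted over the list alone). The median was 3.05 (adjusted p = 5.14e-06, and 0.0213 with an estimated correlation), but 0.66 with normexp background correction. The higher ones included Epcam and Krt19, which the bile duct list also holds, and the lower ones Thy1, at -5.81 (adjusted p = 0.00202). Extracellular matrix, proteases and integrins had 9 members higher and 1 lower of 27 (11 and 6 adjusted over the list alone), with a median of 0.97 (adjusted p = 0.000356). Among them was the protease Mmp7 (at least 157-fold, adjusted p = 0.000122). The direction of the matrix list was not steady, with a median of 1.66 within slide 2 and -0.49 within slide 4, each with 1 array per sort. The Hedgehog and primary cilium list had 3 of 21 higher over all genes and over the list alone (adjusted p = 0.00106). Immediate early and heat shock genes had 4 higher and 1 lower of 24 (7 and 1 adjusted over the list alone), at adjusted p = 0.00355. These last 3 lists were not past the threshold with an estimated correlation (adjusted p = 0.0964, 0.0566 and 0.358).

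Genes of hepatocytes, endothelium, stellate cells and erythroid cells were lower in M+133+ than in M-133- cells. Among 27 hepatocyte genes 23 were lower and 0 higher (25 and 0 adjusted over the list alone), with a median of -6.23 (adjusted p = 7.32e-23). Examples are Tdo2, which degrades tryptophan (-9.68, adjusted p = 4.54e-05), and Otc of the urea cycle (-8.83, adjusted p = 0.00155). Of 22 endothelial genes 17 were lower (21 adjusted over the list alone), with a median of -5.55 (adjusted p = 2.98e-17), including Stab2, a scavenger receptor of sinusoids (-6.89, adjusted p = 0.000281). Stellate cell and fibroblast genes had 10 of 22 lower (12 lower and 1 higher adjusted over the list alone), with a median of -2.76 (adjusted p = 2.64e-07). Erythroid and platelet genes had 5 of 10 lower (6 adjusted over the list alone), with a median of -4.36 (adjusted p = 1.75e-05). Genes of heme metabolism had 4 of 17 lower (6 adjusted over the list alone), with a median of -1.03 (adjusted p = 0.00454). These 5 lists held with an estimated correlation (adjusted p from 0.0213 to 0.0303), although normexp background correction ended the heme call (adjusted p = 0.109). Some of the largest single decreases have fitted sizes against signals at background. Paqr9 and Gata2 stood at -9.36 to -8.93 and at -8.89 to -8.63 in M+133+ untreated samples 2 to 4, dimmer than any value called well above background there. The largest decreases were in Cyp2c40 (-10.65), Ugt1a9 (at least 426-fold), Serpina3n (-10.12), Paqr9 (-10.02), Aox3 (-9.82) and Gata2 (-9.79). Paralogs make the identity of the first 3 uncertain, and Serpina3n lost its call without M-133- untreated sample 1 (adjusted p = 0.0504).

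Immune lists gave little in this comparison. Macrophage genes were called 2 higher and 2 lower of 22, over all genes and over the list alone, and the list was not past its test (median -2.24, adjusted p = 0.0833). Its mean per sample was -1.07 in M-133- untreated sample 1 and -4.76 in sample 2. Chemokines, cytokines and acute phase genes had 3 higher and 6 lower of 24 (4 and 8 adjusted over the list alone), at adjusted p = 0.0293, and 0.22 with an estimated correlation. That call was also lost with normexp, without the probe filter and with slide as a fixed block (adjusted p = 0.098, 0.114 and 0.0644). The lists for B cells (adjusted p = 0.91), T and NK cells (0.91), neutrophils (0.721), proliferation (0.347), Nrf2 (0.147), interferon response (0.157), Notch (0.91) and Wnt (0.767) were not past the threshold. The Notch list had 2 higher and 2 lower of 18 (2 and 4 adjusted over the list alone).

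In all, 2072 of 23281 genes differed (832 higher and 1240 lower in M+133+ cells; 4571 at an unadjusted p under 0.05), with a median SE of 0.99. Of these, 285 had a group with no array well above background. The excess of lower genes depended on the scaling and on single samples, with 1061 higher and 1074 lower under quantile normalization and 528 and 1281 under normexp. Slide as a fixed block gave 2392 genes. With only the first of the repeat arrays 843 were higher and 1440 lower, and with only the second 831 and 990. Without M-133- untreated sample 1 or sample 2, 819 and 1228 genes were called (418 higher and 401 lower, and 434 and 794), of which 736 and 985 were shared with the 2072.

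After DDC the same question was asked of the injured liver. M+133+ cells again had higher levels of bile duct genes. Krt19 was 855-fold higher (log2 difference 9.74, SE 0.66, adjusted p = 5.06e-07; 5.97 ± 1.12, n = 4, against -3.77 ± 1.04, n = 4) and Epcam 504-fold (8.98, SE 0.59, adjusted p = 4.36e-07). Of 28 bile duct genes 22 were higher and 1 lower (25 and 1 adjusted over the list alone), with a median of 4.38 (adjusted p = 2.46e-19). Of 30 junction and keratin genes 19 were higher and 1 lower (23 and 1 adjusted over the list alone), with a median of 2.88 (adjusted p = 8.83e-14). Both held with an estimated correlation (adjusted p = 0.00194 and 0.00127). Among the largest increases were Adgrg7 (at least 1370-fold, adjusted p = 7.99e-07), Cltrn, a collectrin (at least 583-fold, adjusted p = 1.9e-07), and Tmem45b (at least 574-fold, adjusted p = 7.86e-06). Others were Spink4, a serine protease inhibitor (log2 difference 11.07, adjusted p = 2.91e-06), Rab25, an epithelial Rab protein (10.92, adjusted p = 4.5e-06), and Chil4, a chitinase-like protein whose probe can read Chil3 (at least 905-fold, adjusted p = 1.55e-05).

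Matrix genes had 11 higher and 5 lower of 27 after DDC (the same counts adjusted over the list alone), with a median of 1.13 (adjusted p = 0.00159). Progenitor markers had 7 higher and 2 lower of 19 (9 and 2 adjusted over the list alone), at adjusted p = 0.0192. Hedgehog and cilium genes had 5 higher and 1 lower of 21 (7 and 1 adjusted over the list alone), at adjusted p = 0.0199. These 3 were not past the threshold with an estimated correlation (adjusted p = 0.138, 0.138 and 0.153).

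Stellate cell, endothelial and hepatocyte genes were the lists with the lowest medians in M+133+ cells after DDC. Stellate and fibroblast genes had 18 of 22 lower (20 adjusted over the list alone), with a median of -5.89 (adjusted p = 1.86e-19). Examples are Dcn, which encodes decorin (-9.53, SE 1.51, adjusted p = 0.00066), and Lrat, which esterifies retinol (-7.77, adjusted p = 0.000603). Endothelial genes had 20 of 22 lower (22 adjusted over the list alone), with a median of -5.12 (adjusted p = 1.86e-19). Hepatocyte genes had 22 of 27 lower (23 adjusted over the list alone), with a median of -5.90 (adjusted p = 2.13e-21). Interferon response genes had 11 of 21 lower (12 lower and 1 higher adjusted over the list alone), with a median of -1.91 (adjusted p = 3.06e-07). Ifit1, an interferon-induced protein, was among them (-4.01, adjusted p = 0.0035). Heme metabolism had 7 of 17 lower (8 adjusted over the list alone), with a median of -1.26 (adjusted p = 3.34e-05). Erythroid genes had 4 of 10 lower (5 adjusted over the list alone), with a median of -1.82 (adjusted p = 8.41e-05). These 6 lists held with an estimated correlation (adjusted p from 0.00194 to 0.0408).

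The largest decreases after DDC were in Kcnj8 (-10.93) and Abcc9 (-10.16), subunits of an ATP-sensitive potassium channel, Colec10 (-10.55), Hsd3b3 (-10.50), Pdilt (at least 328-fold, adjusted p = 7.76e-07) and Tmem47 (at least 342-fold, adjusted p = 2.84e-05). In M+133+ DDC sample 1, Dcn stood at 1.71 against -6.89 to -5.07 in the others of its group.

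Chemokine and acute phase genes had 4 higher and 9 lower of 24 (5 and 12 adjusted over the list alone), at adjusted p = 0.00112, and 0.071 with an estimated correlation. Saa1 and Saa2, acute phase proteins of near-identical sequence, differed by -5.84 and -6.40. Nrf2 genes had 2 higher and 7 lower of 19 over all genes and over the list alone (adjusted p = 0.0192, and 0.196 with an estimated correlation). That call was lost with quantile normalization and with slide as a fixed block (adjusted p = 0.4 and 0.248). Macrophage genes had 1 higher and 1 lower of 22 over all genes and over the list alone (adjusted p = 0.0301, and 0.409 with an estimated correlation). It lost its call with normexp, with slide as a fixed block and without M+133+ untreated sample 2 and M+133+ DDC sample 1 (adjusted p = 0.0565, 0.196 and 0.0975). Proliferation (adjusted p = 0.401), B cell (0.536), T and NK cell (0.88), neutrophil (0.354), Notch (0.536), Wnt (0.521) and immediate early genes (0.536) were not past the threshold. By the exact permutation test of list means, the 14 lists called here had p = 0.0286, the smallest possible (0.05 after adjustment), except macrophage (p = 0.143) and Nrf2 genes (p = 0.0857).

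In all, 3015 genes differed after DDC (1452 higher and 1563 lower; 5966 at an unadjusted p under 0.05, and 335 of the called with a group at background), with a median SE of 0.81. No slide held both sorts of DDC samples, so no value within a slide can be had. Slide as a fixed block, which reaches this comparison through the untreated arrays alone, gave 1226 genes. With the mean of a gene's probes the balance turned, to 1821 higher and 1563 lower, and without the intensity trend it was 1349 and 1345.

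The sort difference was shared between treatments for many genes. Of 23281 genes, 478 were higher and 731 lower in M+133+ cells in both, where independent lists would share 51.9 and 83.2. The 2 comparisons use different samples, and their log2 differences correlated at 0.62 across genes. They share the same estimate of each gene's spread, so a gene of small spread is called more easily in both. The numbers for independent lists are therefore likely too low a baseline. Without M-133- untreated sample 1 or sample 2 the shared genes numbered 535 and 704 in place of 1209.

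**Figure D2:**
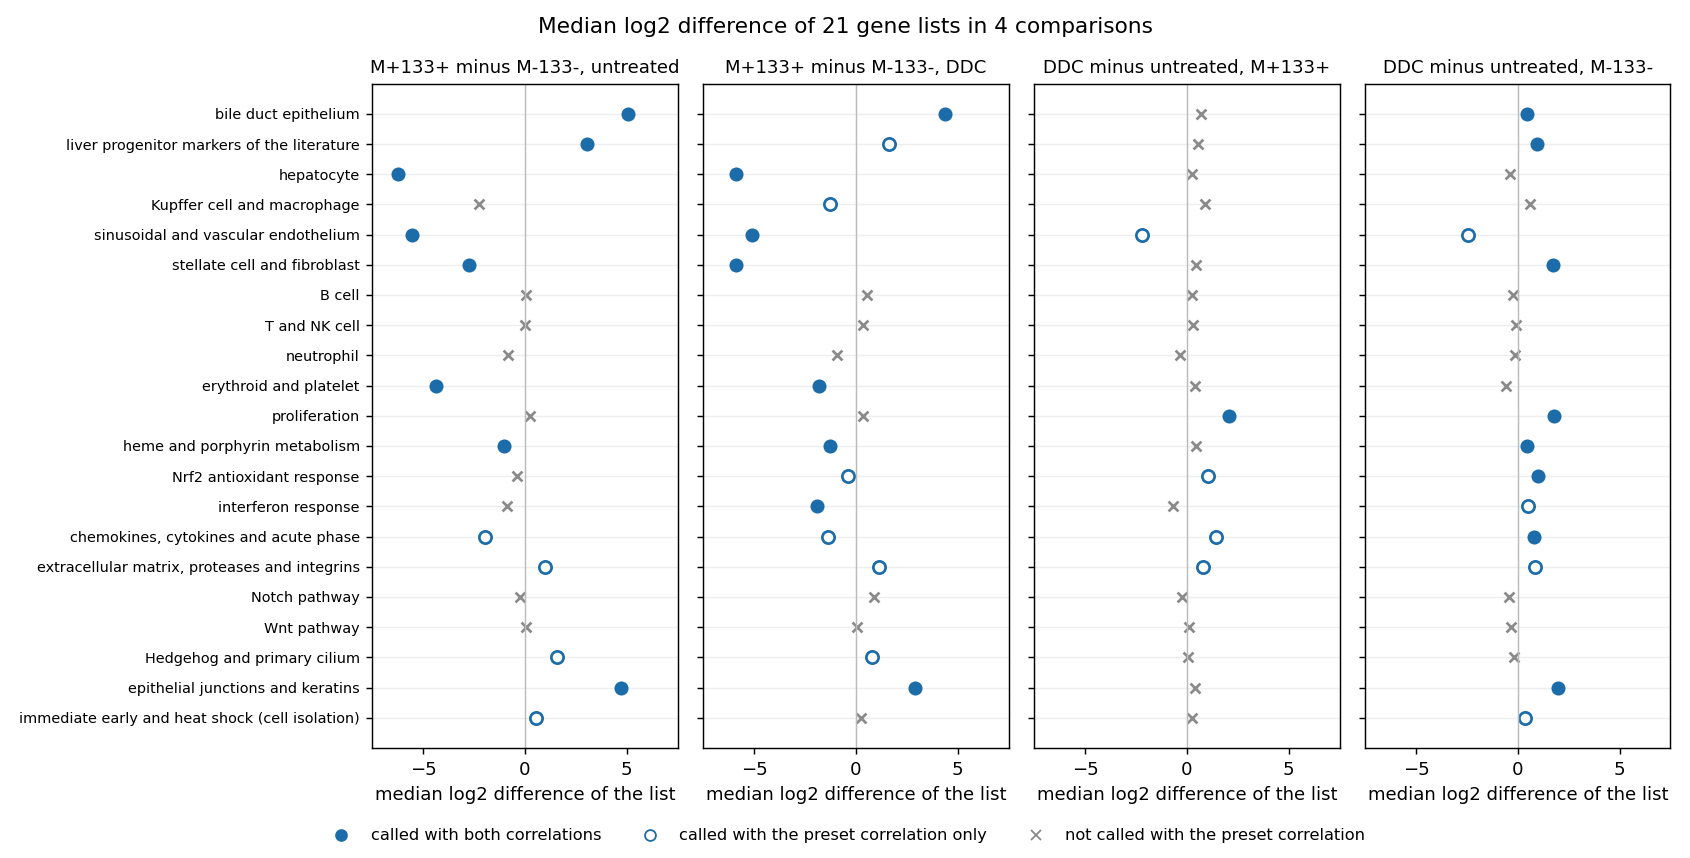
Median log2 difference of each of the 21 gene lists (horizontal axis) in the sort comparisons and the DDC comparisons; filled points are lists called with both the preset and the estimated correlation, open points those called with the preset correlation only, and crosses those not called. Bile duct genes had medians of 5.07 and 4.38 in the sort comparisons and proliferation genes 2.06 and 1.77 in the DDC comparisons.

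The effect of DDC within M+133+ cells was smaller in number of genes. Genes of cell division rose as a group. The median of 30 proliferation genes was 2.06, and 29 of them had a positive difference. Over all genes 3 passed (22 adjusted over the list alone), namely Mki67, a marker of dividing cells (2.15, SE 0.39, adjusted p = 0.0364), Ccna2, cyclin A2 (4.10, adjusted p = 0.0439), and the mitotic kinase Aurkb (5.98, adjusted p = 0.0364). The list mean per sample was 1.49 ± 0.24 after DDC against -0.81 ± 0.76 untreated (SD, n = 4 each; exact permutation p = 0.0286, the smallest possible, 0.1 after adjustment). The list test gave adjusted p = 2.6e-18, or 0.0232 with an estimated correlation. Medians within slides 3 and 4, which held both treatments, were 1.56 and 2.54. Chil3, a chitinase-like protein, rose by 7.91 (SE 0.71, adjusted p = 0.000319; 2.77 ± 0.78 against -5.14 ± 0.66, n = 4 each) and Chil4 by 9.63 (adjusted p = 0.00352). The size for Chil4 is a fitted value and no measured size. It stood at -8.54, -7.21 and -7.38 in M+133+ untreated samples 1, 3 and 4, dimmer than any value called well above background on their arrays. Sample 2 stood at -2.17. Chil3 and Chil4, which their probes may not separate, kept their calls under every alternative run.

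Other increases in M+133+ cells after DDC were in Anln, an actin-binding protein of cytokinesis (6.79, adjusted p = 0.0188), Cdc25c, a phosphatase of mitotic entry (6.91, adjusted p = 0.0329), and the adhesion molecules Cdh17 (at least 47.3-fold, adjusted p = 0.0188) and Vcam1 (2.35, adjusted p = 0.0188). Others were the chemokine Ccl2 (5.02, adjusted p = 0.0197), Gsta2, a glutathione transferase (3.07, adjusted p = 0.0188), and Samd5 (8.81, adjusted p = 0.0329). Dnah5, a dynein of motile cilia, had a difference of -6.86 (adjusted p = 0.0122), Ank2 of -5.95 and Exoc3l2 of -5.83 (adjusted p = 0.0188 for both). Also lower were Arap3 (-6.42, adjusted p = 0.0412), Colec10 (-6.05, adjusted p = 0.0368) and Zfp287 (-5.17, adjusted p = 0.0439).

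Among the other lists in M+133+ cells, chemokines had 2 of 24 higher after DDC (7 adjusted over the list alone), with a median of 1.43 (adjusted p = 0.000172). Nrf2 genes had 1 of 19 higher (2 adjusted over the list alone), with a median of 1.06 (adjusted p = 1.84e-05). Matrix genes had 1 of 27 higher over all genes and over the list alone (median 0.78, adjusted p = 0.000462). Endothelial genes had 0 of 22 called (2 lower adjusted over the list alone), with a median of -2.21 (adjusted p = 1.21e-08). None of these 4 held with an estimated correlation (adjusted p = 0.0939, 0.0939, 0.229 and 0.231). The exact permutation test of list means gave p = 0.0286 (0.1 after adjustment) for the first 3 and for heme and junction genes, and 0.0571 (0.171 after adjustment) for endothelial genes. The bile duct (adjusted p = 0.22), progenitor (0.0511), hepatocyte (0.485), macrophage (0.35), stellate (0.485), B cell (0.696), T and NK cell (0.684), neutrophil (0.696), erythroid (0.446) and heme lists (0.396) were not past the threshold. Neither were the interferon (0.111), Notch (0.469), Wnt (0.789), Hedgehog (0.37), junction (0.0511) and immediate early lists (0.696).

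In all, 63 genes differed between DDC and untreated M+133+ cells (40 higher and 23 lower; 2916 at an unadjusted p under 0.05, and 5 of the called with a group at background). Slide as a fixed block gave 30. Without M+133+ untreated sample 3, sample 4 or sample 1 the counts were 6, 6 and 40, without M+133+ DDC sample 4 or sample 3 they were 11 and 110. The balance turned to 36 higher and 51 lower without M+133+ DDC sample 2, to 19 and 21 without M+133+ untreated sample 1, and to 10 and 12 without the intensity trend. The other 20 of the 22 genes named by the rule each lost the call when some sample was left out. The share of genes recovered in simulated data was low at 4-fold (5%), so an absent call says little.

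In M-133- cells, single genes of the bile duct and keratin lists were higher after DDC. The lists for stellate cells, cell division and inflammation shifted upward. This sort held transcripts of hepatocytes, endothelium, stellate cells and erythroid cells. A change within cells and a change in their mix were not told apart. Lcn2, which encodes lipocalin 2, rose by 9.18 (SE 1.02, adjusted p = 0.000463; 2.76 ± 0.39, n = 4, against -6.42 ± 1.63, n = 2), Spp1 by 8.81 (adjusted p = 8.74e-05) and Krt8 by 3.58 (SE 0.38, adjusted p = 0.00032; 6.05 ± 0.65 against 2.47 ± 0.15). The oncofetal gene Afp was at least 153-fold higher (adjusted p = 0.0152) and Ubd, a ubiquitin-like modifier, at least 410-fold (adjusted p = 0.00744). Sprr1a, a small proline-rich protein, was at least 442-fold higher (adjusted p = 8.05e-06) and Hs3st3a1, a heparan sulfate sulfotransferase, at least 146-fold (adjusted p = 8.74e-05). Epcam and Krt19 differed by 1.98 and 0.41 (adjusted p = 0.238 and 0.903). Progenitor markers had 5 of 19 higher (7 higher and 1 lower adjusted over the list alone), with a median of 0.92 (adjusted p = 1.04e-06). They included Sox9, a transcription factor of bile ducts (3.36, adjusted p = 0.021), and Tnfrsf12a, the receptor of TWEAK (4.44, adjusted p = 0.00544). Junction and keratin genes had 5 of 30 higher (9 higher and 1 lower adjusted over the list alone), with a median of 1.98 (adjusted p = 3.37e-11). Bile duct genes had 2 of 28 higher (5 adjusted over the list alone) at adjusted p = 1.04e-06, with a median of 0.47 that was -0.02 with normexp background correction.

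Stellate and fibroblast genes in M-133- cells had 3 of 22 higher after DDC (6 adjusted over the list alone), with a median of 1.71 (adjusted p = 5.77e-09). Among them was Des, which encodes desmin (5.51, adjusted p = 0.0132). Proliferation genes had 2 of 30 higher (13 higher and 1 lower adjusted over the list alone), with a median of 1.77 (adjusted p = 4.94e-13), such as Birc5, survivin (4.06, adjusted p = 0.0152). Nrf2 genes had 0 of 19 called (5 higher adjusted over the list alone), with a median of 1.01 (adjusted p = 1.04e-06). Chemokine and acute phase genes had 2 of 24 higher (8 adjusted over the list alone), with a median of 0.80 (adjusted p = 1.04e-06). Heme metabolism had 0 of 17 called over all genes and over the list alone (median 0.44, adjusted p = 0.0124), a call lost with quantile normalization (adjusted p = 0.0976). With an estimated correlation these 5 lists and the bile duct, progenitor and junction lists held (adjusted p from 0.0027 to 0.0416).

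Endothelial genes in M-133- cells had a median of -2.45 after DDC (adjusted p = 1.04e-06), with 0 of 22 called (1 lower adjusted over the list alone). Interferon genes had a median of 0.49 (adjusted p = 0.0047, and 0.073 with quantile normalization), with 0 of 21 called over all genes or over the list alone. Matrix genes had a median of 0.83 (adjusted p = 0.00113), with 0 of 27 called (8 higher and 2 lower adjusted over the list alone). Immediate early genes had a median of 0.32 (adjusted p = 0.00115), with 2 of 24 higher (3 adjusted over the list alone). Those 4 did not hold with an estimated correlation (adjusted p = 0.188, 0.161, 0.149 and 0.291).

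The largest decreases in M-133- cells after DDC were in Plxdc1 (at least 208-fold, adjusted p = 0.000463), Gpr21, an orphan receptor (-9.26, adjusted p = 0.007), and Stox1 (-7.60, adjusted p = 0.00367). Others were Sult3a2, a sulfotransferase with close paralogs (adjusted p = 0.0228, and 0.228 without M-133- untreated sample 1, which stood at 5.23 against -3.39 in sample 2), Cd209b, a lectin (-7.98, adjusted p = 0.0299), and Zfp84 (-7.22, adjusted p = 0.0175). Hepatocyte (adjusted p = 0.916), macrophage (0.187), B cell (0.704), T and NK cell (0.923), neutrophil (0.908), erythroid (0.916), Notch (0.272), Wnt (0.279) and Hedgehog lists (0.916) were not past the threshold. In all, 227 genes differed (144 higher and 83 lower; 2967 at an unadjusted p under 0.05, and 36 of the called with a group at background). The balance turned with the scaling, to 111 higher and 142 lower under normexp, against 162 and 52 under quantile normalization. Slide as a fixed block gave 260. With only the first or only the second of the repeat arrays, 333 and 211 genes were called. Without M-133- untreated sample 1 the count was 74 (59 shared), and without sample 2 it was 229 (89 shared, 77 higher and 152 lower). Among the 30 named genes 17 and 18 lost their call, Afp and Ubd in both cases, while Lcn2, Spp1, Krt8, Sprr1a, Hs3st3a1 and Plxdc1 kept theirs under every alternative run. With only the M-133- samples in the fit, 38 genes were called.

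**Figure D3:**
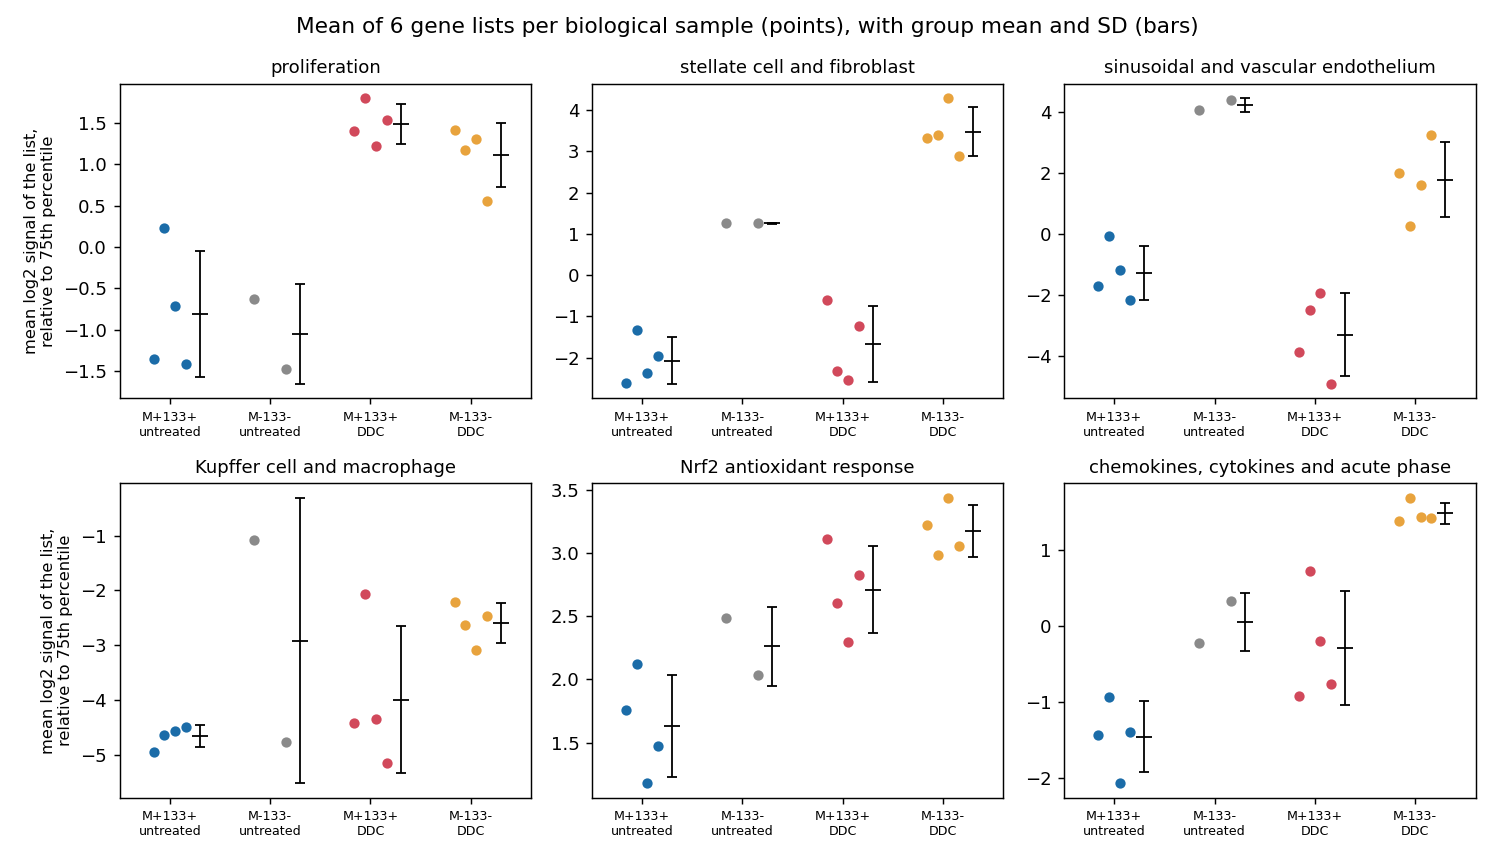
Mean log2 signal of 6 gene lists relative to the 75th percentile of the array (vertical axis) in the 4 groups; points are biological samples and bars are the group mean and SD. Proliferation means lay between 1.22 and 1.80 in M+133+ cells after DDC and between -1.41 and 0.23 in untreated ones.

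The interaction asked whether the sort difference itself changed with DDC. It did for 61 genes, 14 with a larger and 47 with a smaller signed M+133+ minus M-133- difference after DDC (2318 at an unadjusted p under 0.05, median SE 1.28). A smaller signed difference can mean that the gap between sorts narrowed, widened or reversed. Osbpl3, for example, stood at 0.23 in M+133+ and -7.51 in M-133- cells untreated, and at -0.77 and 0.59 after DDC. Spp1 differed by 10.43 between sorts in untreated livers and by 1.64 after DDC, a change of -8.79 (SE 1.05, adjusted p = 0.00198), and Krt8 by 3.21 and 0.25, a change of -2.96 (adjusted p = 0.0234). The sort differences of Bex2 (adjusted p = 0.0234), Lama1, a laminin chain (adjusted p = 0.00433), and Osbpl3 (adjusted p = 0.00198) moved downward. Those of Chil4 (adjusted p = 0.0355), Chil3 (9.92, adjusted p = 0.00169) and Plxdc1 (adjusted p = 0.00433) moved upward. The fitted sizes of these genes other than Chil3 are not measured sizes, since a group had no array well above background.

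Junction and keratin genes had a median interaction of -1.18 (adjusted p = 6.12e-05), with 3 of 30 lower (5 lower and 1 higher adjusted over the list alone). Stellate genes had a median of -1.05 (adjusted p = 6.12e-05), with 2 of 22 lower (3 adjusted over the list alone). Interferon genes had a median of -1.35 (adjusted p = 0.00128), with 0 of 21 called (1 lower adjusted over the list alone). Bile duct genes had a median of -0.51 (adjusted p = 0.00434), with 1 of 28 lower (2 adjusted over the list alone). Progenitor markers had a median of -0.25 (adjusted p = 0.0083), with 1 of 19 lower (5 adjusted over the list alone). Immediate early genes had a median of -0.25 (adjusted p = 0.0241), with 1 of 24 lower (2 adjusted over the list alone). None of the 6 held with an estimated correlation (adjusted p = 0.0576, 0.184, 0.184, 0.274, 0.184 and 0.751). The medians of bile duct and progenitor genes were 0.50 and 0.57 with normexp, and slide as a fixed block ended the calls of both (adjusted p = 0.0523 and 0.104).

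The other 15 lists were not past the interaction test, with adjusted p from 0.355 upward. Counts for the interaction moved with single samples. They were 28, 25, 24 and 19 without M+133+ untreated samples 1 to 4. They were 35 and 104 without M-133- untreated samples 1 and 2 (5 larger and 30 smaller, and 74 larger and 30 smaller, so that the balance turned in the latter), 38 and 23 without M+133+ DDC samples 1 and 4, and 36 without M-133- DDC sample 1. With slide as a fixed block 19 genes were called, and Spp1, Krt8, Bex2, Chil4 and Plxdc1 lost their calls; Bex2, Lama1 and Osbpl3 lost theirs with normexp. Without M+133+ untreated sample 2 and M+133+ DDC sample 1, left out together for their Dcn levels (1.17 and 1.71) and the Y-linked transcripts of the first, 30 were called. M+133+ DDC sample 2 had the highest hepatocyte and macrophage list means of its group (0.49 and -2.06), and 48 were called without it.

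DDC moved 2 genes the same way in both sorts, namely Sprr1a (3.54 in M+133+ cells, adjusted p = 0.0344) and Cdc25c (6.91, and 8.42 in M-133- cells, adjusted p = 0.0329 and 0.0128), where independent lists would share 0.247 higher and 0.082 lower. Here too the calls share the same estimate of the spread, so that baseline is likely too low. The DDC differences in both sorts correlated at 0.16 across genes. Each of these 2 genes lost a call without M+133+ untreated sample 3, sample 4 or M+133+ DDC sample 4, which left 0 shared genes. Proliferation genes were the list called in both sorts with both correlations. In 15 of the list tests over all 5 comparisons the median, the mean and the test differed in sign, and 0 of these were called.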

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

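The tests for M+133+ cells within the M-133- DDC sort and for shared untreated samples, both tests on the library with low Xist and both tests on Chil3 and Chil4 were chosen only after the result was seen. The tests of array scaling, of slide and of other splits of the samples were written down before.

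Genes that M+133+ cells held at higher levels in untreated livers were also higher in M-133- cells after DDC. Of the 832 genes higher in untreated M+133+ cells, 83 were among the 144 higher in M-133- cells after DDC. The fits share the same estimate of each gene's spread, so the numbers given below for independent lists are likely too low a baseline. Both comparisons use the same 2 M-133- untreated samples, whose errors alone would put genes in both lists; with 1 of them as the control of each comparison, so that none was shared, 41 and 37 genes were called in both, where independent lists would share 1.38 and 1.16, although genes low in M-133- cells have more room to rise. Array scaling and slide leave the pattern in place in part: 57 of the 83 were still called with normexp, 78 with quantile normalization and 68 with slide as a fixed block, and without M-133- untreated sample 1 or sample 2, 43 and 54 were called. M+133+ cells left in the M-133- DDC sort would bring all their abundant transcripts, but the gain of the bile duct list amounted to a median 0.38% of the M+133+ DDC level (quartiles 0.0353% and 10.3%, 22 members) against 66.3% for the 83 genes (25.9% and 99.3%), which were selected for their rise, and 3.48% for all 832 (-0.275% and 20.9%), with Epcam and Krt19 low and Spp1 and Krt8 high. A response of M-133- cells to DDC, or another kind of cell in that sort after DDC, may explain the 83 genes and was not tested.

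M+133+ untreated sample 2 had the lowest Xist, the transcript of the inactive X chromosome, at -3.44 against 2.85 to 5.51 in the 13 other samples, though still well above background. A male mouse as its source is a candidate explanation: 4 of 4 Y-linked genes were well above background there and in 0 of the 13 others, namely Ddx3y (0.51), Eif2s3y (1.33), Kdm5d (-1.97) and Uty (-1.54), signals that no comparison of the report used. A sample of the other sort under this label is argued against, since the median correlation across genes was 0.753 with the M-133- untreated arrays and 0.879 with the other M+133+ untreated ones. Without this sample 1662, 66 and 25 genes were called for the untreated sort comparison, DDC in M+133+ cells and the interaction. The labels give no sex, so sex was not compared.

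Chil3 and Chil4, which macrophages can express, rose in M+133+ cells after DDC by 7.91 and by a fitted 9.63. Before DDC, Chil4 stood at -2.17 in sample 2 but at -8.54, -7.21 and -7.38 in samples 1, 3 and 4. Macrophages or neutrophils in that sort would bring their other transcripts, yet the list medians were 0.90 and -0.35. Of the abundant macrophage genes, Cd5l stood at 2.92 and -0.02, Marco at 2.18 and -0.50 and Lyz2 at 0.24 and -5.84 in M+133+ DDC samples 2 and 3, which may hold macrophages, but Cd5l at -5.11 and -4.77, Marco at -2.00 and -5.41 and Lyz2 at -6.29 and -6.36 in samples 1 and 4, where Chil3 still reached 3.02 and 2.24. Other macrophage genes did not all split the samples in this way. In M+133+ DDC samples 1 to 4, Cd68 stood at -0.67, -2.42, 0.53 and -2.50, and C1qb at -2.09, -2.22, -4.70 and -4.64. Vsig4 stood at -4.26, -1.28, -7.73 and -7.18. In M-133- DDC samples, Lyz2 ran from -0.86 to 2.28 while Chil3 ran from -8.36 to -5.76. Induction within the sorted M+133+ cells may explain the rise and remains a hypothesis found in these data.

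The sort difference of several named genes changed with DDC by the interaction test: upward for Chil4 (10.35), Chil3 (9.92) and Plxdc1 (9.17), and downward for Bex2 (-9.60), Lama1 (-9.16), Osbpl3 (-9.10), Spp1 (-8.79), Des (-6.62) and Krt8 (-2.96). Of 29 alternatives, Des lost its call in 19, Chil4 in 13, Krt8 in 9, Bex2 in 8, Plxdc1, Lama1, Osbpl3 and Spp1 in 1 each and Chil3 in 0. The sizes for Chil4, Plxdc1, Bex2, Lama1 and Osbpl3 are fitted values and no measured sizes, since at least 1 group had no array well above background: M-133- DDC cells for Chil4 and Plxdc1, and M-133- untreated cells for Chil4, Bex2, Lama1 and Osbpl3. For Lama1 this also held for M+133+ DDC cells.

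Single samples stood apart from the other 3 of their group in 27 of 288 groups of 4 values, by the ratio of the gap to the range. Chance gives about 5%, or 14.4 groups. The ratio ignores the size of the gap, which can be small among values at background. Dnah5, for example, stood at -8.01 against -8.48 to -8.42, and Lama1 at -7.85 against -8.65 to -8.58. In M+133+ untreated cells these were sample 1 for Paqr9 (-6.63), Gata2 (-4.96), Pdilt (-8.30), Stox1 (-5.88) and the Notch list mean (-0.67), sample 2 for Tmem47 (-3.17) and Samd5 (-2.15), sample 3 for Gpr21 (0.19) and Zfp84 (2.06), and sample 4 for Sox9 (5.01). In M+133+ DDC cells they were sample 1 for Tmem47 (-6.99), Hs3st3a1 (-7.24) and Lama1 (-7.85), sample 2 for Otc (-1.79), Aox3 (-1.31) and the junction and keratin mean (2.02), and sample 3 for Stab2 (-1.05). In M-133- DDC cells they were sample 1 for Mki67 (3.38) and Des (0.86), sample 2 for Birc5 (4.97), sample 3 for Dcn (6.41), Kcnj8 (4.91), Dnah5 (-8.01), the heme mean (3.01) and the immediate early mean (4.53), and sample 4 for Aurkb (-5.83) and Cd209b (-0.31).

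Other splits of the samples were counted where both groups had 4. For the sort comparison after DDC, 1 of 35 splits, the real one, gave as many genes (3015, and the highest other gave 39). Likewise 1 of 35 gave as many gene lists, with 14 against 12 in the highest other, a small margin. Since 1 of 35 is the smallest share possible, chance is not excluded for either count. A wrong split also keeps the real difference within its groups, which lowers its count of genes. No slide held both sorts of DDC samples, so these splits cannot separate sort from slide. For DDC in M+133+ cells, 1 of 35 gave as many genes (63, and the highest other gave 3). That is again the smallest share possible, so chance is not excluded. As many lists came from 14 of 35 splits (5, with 9 in the highest other), so chance cannot be excluded for the number of lists. The other comparisons have a group of 2 and were not split.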

How the results depend on the processing

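The fit without M+133+ untreated sample 2 and M+133+ DDC sample 1, and slide as a fixed block for the gene lists, were chosen after seeing the data; the other alternatives were planned. The scan date gave no value, since every array was scanned on 1 day. Where no reason is named, the cause was not tested.

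The count for the sort comparison in untreated livers (2072) stayed within 1.5 times under the alternatives run on all samples, and ran from 819 to 2242 with 1 sample left out. After DDC (3015) it was 1226 with slide as a fixed block, which leaves few arrays to inform it, and 2401 to 2992 with 1 sample left out. Genes shared by both sort comparisons (1209) numbered 535 to 1215 with 1 sample left out. Leaving out an M-133- untreated sample leaves 1 in that group, assumed to vary like the others.

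For DDC in M+133+ cells (63 genes) the counts were 137 with quantile normalization, 40 with only the compared groups in the fit, 22 without the intensity trend, 143 with array weights, 103 with 16 arrays and the sample as a random block, and 119 and 30 with slide as a random and a fixed block; 1 sample left out gave 6 to 110. For DDC in M-133- cells (227) they were 38 with only the compared groups, 525 with 16 arrays and 582 with slide as a random block; 1 sample left out gave 74 to 276. For the interaction (61) they were 40 with normexp, 37 without the trend, 116 with 16 arrays, 117 and 19 with slide as a random and a fixed block, and 30 without the 2 samples named above; 1 sample left out gave 19 to 104. Entering repeat arrays singly counts 2 samples more heavily.

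Genes moved the same way by DDC in both sorts (2) numbered 8 with quantile normalization, 4 with normexp, 4 with the stricter filter on dim probes, 6 with the mean of all kept probes, 1 with only the compared groups, 0 without the trend, 7 with array weights, 17 with 16 arrays, 19 and 0 with slide as a random and a fixed block, 6 with the first of the repeat arrays and 6 without the 2 samples; 1 sample left out gave 0 to 7.

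The replicate numbers in titles and descriptions conflict, and the labels do not say which samples came from the same livers. Samples of the same title number correlated at -0.013 to 0.113 after the group means were removed, and 2 of 4 DDC samples were closest to their own number, so pairing was not shown and stays open, and the numbers served as a block here alone. Samples of both sorts with the same title number also had close hybridization numbers, such as 12 and 13 for title number 5. The correlation that limma estimated within title numbers was 0.096. With the title number as a random block, 2256 genes were called for the sort comparison in untreated livers and 3413 after DDC. These included all 2072 and 3015 of the main calls. As a fixed block within DDC, the title number gave 1720 genes for the sort comparison after DDC. The number in the descriptions as a block gave 6 for DDC in M+133+ cells, 117 for DDC in M-133- cells, 24 for the interaction and 0 moved by DDC in both sorts.

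Of the gene list tests over all 5 comparisons, 49 were called, and 25 with an estimated correlation; 0 were called in the opposite direction under the 6 alternatives run for lists (quantile normalization, normexp, no filter, estimated correlation, slide as a fixed block and the 2 samples left out). Of the named genes, 37 of 84, 55 of 82, 2 of 22, 6 of 30 and 1 of 13 kept their call in every alternative, in the order sort untreated, sort after DDC, DDC in M+133+ cells, DDC in M-133- cells and interaction. The direction of 1 named gene reversed: Fth1, at -1.20 in the untreated sort comparison, was 0.26 with quantile normalization. Between 59.8% and 77.1% of probes per array were well above background, and folds against groups at background are bounds.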

Other observations

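No test in this part was chosen after a result was seen, since none was run; the genes named were chosen after their values were seen.

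Few genes differed between the sorts in opposite directions in the 2 treatments. There were 6 such genes, against 1209 in the same direction, and those without a clone-like identifier are named here. Some calls at this threshold are false in each comparison, so some of the 6 may have no change of direction. Atoh8, a transcription factor of the bHLH family, was 2.59 higher in M+133+ cells of untreated livers (adjusted p = 0.0257) and differed by -2.00 after DDC (adjusted p = 0.0253). Tmem141 differed by 3.07 and -2.21 (adjusted p = 0.00787 and 0.0114), and Ttyh1, a chloride channel protein, by 4.39 and -3.69 (adjusted p = 0.0443 and 0.0292). Arhgef25 had mean levels of 2.12 in M+133+ and -1.43 in M-133- cells of untreated livers, and -0.81 and 2.87 after DDC. In the untreated and the DDC comparison, calls were lost in 2 of 30 and 1 of 31 alternatives for both Tmem141 and Arhgef25. They were lost in 6 and 8 for Atoh8 and in 14 and 13 for Ttyh1, with 0 reversed for any of these genes.

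The authors' deposited table gives a fold for each of 4 comparisons. Its log2 folds correlated across probes with those computed here at 0.975 and 0.983 for the sort comparisons in untreated and DDC livers, and at 0.978 and 0.961 for DDC in M+133+ and M-133- cells; the signs were the same for 89.6%, 85.3%, 92.0% and 83.0% of probes. At a deposited false discovery rate of 5% or less it lists 6778 probes (3757 higher and 3021 lower), 3055 (1261 and 1794), 152 (77 and 75) and 68 (65 and 3). Of the genes called here and present in it, 1827 of 2064, 1820 of 3013, 34 of 63 and 27 of 227 were at or under that rate in the same direction. Its test is not stated, so the difference in counts was not traced.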
